A study of Homo sapiens with 6 samples.

How the data were processed

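Total RNA had been extracted with a QIAGEN RNeasy Plus kit and libraries prepared with the TruSeq Stranded mRNA LT kit, per the labels' protocols. The deposited table holds estimated counts per gene, and the submitters' processing notes name Salmon without a version. Genome build, annotation release and the way transcripts were summed to genes are not given in the sources used here. The values are whole numbers as deposited (0 values were not whole), so rounding changed nothing. Rows are versioned Ensembl gene IDs plus 1 row for an optimized SPNS2 sequence, and 20 of 7629 lincRNA genes of GENCODE 29 have a row, so long noncoding RNAs were largely not analysed here. No coordinates are given. Symbols came from a table of gene names, RefSeq and GENCODE 29 for 29145 of 34370 Ensembl IDs, and neighbour order came from RefSeq genes of GRCh38.p14, used only for names and order. GC content and length are those of the longest GENCODE 29 transcript of each gene.

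Samples were grouped by the labels into 3 empty vector and 3 SPNS2 libraries, and all 6 columns of the table were used. Replicate libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 3.19 to 6.45, so none was counted as a duplicate. Counts were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), scaled by TMM (factors 0.993 to 1.01) and tested with the edgeR quasi-likelihood test with group as the only term (edgeR 4.0.16 in R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method, a gene was called at an adjusted p under 0.05 with no minimum fold change, and the standard error was taken as the absolute log2 fold change over the square root of F. Levels are CPM, counts scaled to a common library total, computed with TMM-scaled library sizes, as mean ± SD of 3 libraries. The biological coefficient of variation was 4.32%. Counting intervals are exact 95% Clopper-Pearson intervals of the pooled counts, and a count of 0 was taken to allow up to 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

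Before the data were examined, 43 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 41 lists with at least 5 tested members were tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with SPNS2 left out, and adjusted over lists. Of these, 18 lists passed, 8 up and 10 down. With the correlation estimated per list, 4 were called: interferon response, both proliferation lists, and ATF4 and integrated stress response. Some lists that lost their call had an estimate above the preset value, such as MAPK output (0.0474). Others had an estimate below it, such as antigen presentation class I (-0.0265) and lysosome and autophagy (-0.0222). A higher correlation therefore cannot account for every lost call. Fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 28 lists, including all 18 in the same direction. Antigen presentation class II and long nuclear noncoding RNAs had too few tested members. Some lists overlap: MAPK output and immediate early genes share MYC, EGR1 and FOS, heat shock and MYC targets share HSPD1 and HSPE1, which both fell, and TYMS, KIT and PFKFB4 each stand in 2 lists. Other lists share genes too, so the counts of different lists are not independent.

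Genes were named by this rule: SPNS2; among genes with a symbol, an adjusted p under 0.05, a mean CPM of at least 1 and groups that do not overlap, the 12 largest rises, the 12 largest falls and the 6 smallest p; up to 4 members with the smallest p of each list described; and all members of the MAPK output and sphingosine phosphate lists with the receptors S1PR1 to S1PR5. Genes outside it are said to have been chosen after their values were seen. Some genes and 1 list that these rules cover are not reported here. The plot of interferon genes shows 12 members, more than the rule names, a choice also made after the values were seen.

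The pipeline was tested on simulated counts drawn from the real means and library sizes. For this comparison, with 13204 features simulated, it recovered 40% of genes changed 1.15-fold, 60% at 1.25-fold, 78% at 1.5-fold and 91.8% at 2-fold, and 7 of 141 calls were false. Only 200 genes were given a change there, against 3263 called in the data. The simulated variation between libraries followed a fitted trend and not each gene's own value. The recovered and false shares can therefore differ in the real comparison. In a simulation of lists over 13195 features, 3 of 3 lists shifted by 0.2 on the log2 scale were called, 2 of them with an estimated correlation, and 0 of 37 unshifted lists were called. Each gene was drawn independently there, so the simulation does not show how often lists of co-regulated genes are called falsely. By the recovered shares of genes, small changes can be missed at this depth and number of libraries. Alternatives were DESeq2 size factors, total counts alone, library sizes without the vector row, the DESeq2 1.42.0 Wald test, limma voom, other filters and thresholds, the replicate number as a block, and leaving out each library in turn. DESeq2 adjusted p-values given as missing were left missing.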

Results

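ME-1 is a human acute myeloid leukaemia cell line that carries the CBFB::MYH11 fusion. The cells had received an empty vector or a vector for SPNS2, a transporter that exports sphingosine-1-phosphate, and transduced cells had been selected before RNA extraction. Polyadenylated RNA was sequenced from 6 libraries, 3 with the empty vector and 3 with SPNS2. The series title links SPNS2 to sphingosine metabolism and to MAPK signalling, so the comparison asks how added SPNS2 changed the transcriptome of these cells, with those pathways in view. The count table held 34371 features. Library totals were 38489992, 28605187 and 32468237 counts with the empty vector and 32362204, 31361562 and 33540256 counts with SPNS2. A count of 0 in a single library allows a level of up to 0.0779 to 0.105 CPM at these depths, and such limits cover counting error only. The labels do not say that libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. The first principal component of log2 CPM held 36.6% of the variance and separated the groups.

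The vector SPNS2 sequence had a row of its own in the table, named as an optimized form, apart from the native gene. Its level was 778 ± 12.9 CPM in the SPNS2 libraries (SD, n = 3) and 0.113 ± 0.117 CPM in the empty vector libraries (SD, n = 3). The SPNS2 libraries held 25283, 24792 and 25752 vector counts, and the empty vector libraries held 9, 3 and 0. Pooled over libraries and scaled by their totals, the ratio of vector SPNS2 between groups was 6468, with an exact 95% counting interval of 3703 to 12519. The fitted log2 fold change was 12.61 (SE 0.106). It was 13.83 without empty vector library 1, which held 9 of the 12 vector counts of that group, and 13.23 with limma voom. Native SPNS2 (ENSG00000183018.9) was at 42.6 ± 1.92 CPM with the empty vector and 50.5 ± 1.80 CPM with SPNS2 (SD, n = 3 each). Its log2 fold change of 0.25 (SE 0.0418, adjusted p = 0.00166 by edgeR) was small beside the vector transcript, which stood 15.4 times above native SPNS2 in the SPNS2 libraries. The rise of native SPNS2 equalled 1.02% of the vector level, and reads that match both sequences can be counted for either.

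**Figure D1:**
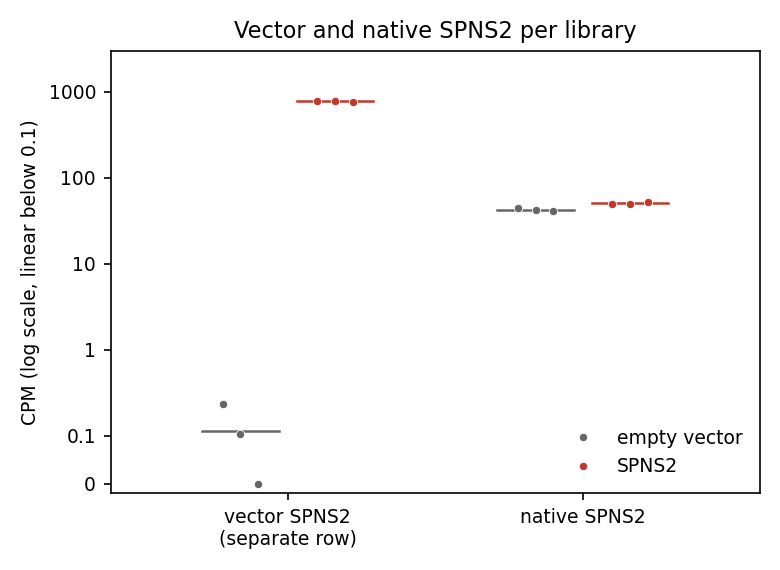
Level of vector SPNS2 and of native SPNS2 in each library, in CPM on a log axis that is linear below 0.1. Points are single libraries and lines are means of 3 libraries; vector SPNS2 lay between 764 and 789 CPM in the SPNS2 libraries and at or below 0.233 CPM in the empty vector libraries.

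Added SPNS2 went with many small changes and few large ones. Of 13308 features tested with edgeR, 3263 (24.5%) passed an adjusted p of 0.05, of which 1580 were higher and 1683 lower in SPNS2. Their median change was 0.21 on the absolute log2 scale, and 2787 of them (85.4%) changed by less than 0.5. Only 81 features rose and 44 fell by more than 2-fold in this fit. The groups did not overlap for 5342 tested features (40.1%), against 10% by chance for 3 libraries against 3.

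Large rises included genes with little expression in control cells. DZIP1 rose from 0.553 ± 0.111 to 5.10 ± 0.429 CPM, and CDKN1C, a cyclin-dependent kinase inhibitor, from 0.890 ± 0.589 to 5.80 ± 0.693 CPM, with log2 fold changes of 3.18 and 2.65 (SD, n = 3 each). ABCG1, a cholesterol exporter, rose by 2.32 on the log2 scale (adjusted p = 7.31e-07 by edgeR). Among more abundant transcripts, ABHD4, a lipase of the N-acyl phospholipid pathway, rose from 35.0 ± 1.42 to 110 ± 2.73 CPM, and TRH, the precursor of thyrotropin-releasing hormone, from 113 ± 5.87 to 305 ± 1.04 CPM (SD, n = 3 each). STON2 was also among the 12 largest rises, as were TRIM6 (1.64), ABLIM1 (1.46), TPSB2 (1.39), SCGB3A1 (1.36) and COL24A1 (1.36 on the log2 scale). TPSB2 is nearly identical to TPSAB1, and the split of reads between both tryptase genes is uncertain. MFAP4 and LGALS3BP, both secreted glycoproteins, rose by 0.75 and 0.73 on the log2 scale, with some of the smallest p-values of the table (adjusted p = 1.06e-08 and 1.64e-08).

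Among the largest falls, FAM83G fell by 2.06 on the log2 scale, from 2.59 ± 0.375 to 0.617 ± 0.0980 CPM, and NID1, a basement membrane protein, fell by 1.95, from 3.91 ± 0.302 to 1.02 ± 0.516 CPM (SD, n = 3 each). HK3, a hexokinase of myeloid cells, had a log2 fold change of -1.79 and MNDA, a nuclear antigen of myeloid cells, one of -1.51. SDC4, a heparan sulphate proteoglycan, fell by 1.46, CSTA, a cysteine protease inhibitor, by 1.41, LOXHD1 by 1.38, EDIL3 by 1.37, SRPX by 1.37 and CRIM1 by 1.26. LCP1, the leukocyte actin-bundling protein L-plastin, fell from 99.1 ± 1.36 to 45.0 ± 1.29 CPM (SD, n = 3 each; log2 fold change -1.14, adjusted p = 3.13e-09 by edgeR). SLC39A4 had a log2 fold change of -1.23 (adjusted p = 0.0345) that rested on empty vector library 3, without which it was -0.56 (adjusted p = 0.105). The adjusted p of SLC39A4 was also above the threshold without SPNS2 library 1 (0.0621), 2 (0.114) or 3 (0.0956) and with limma voom (0.0821).

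Transcriptional targets of the MAPK pathway were lower with SPNS2. Of 17 tested genes in the MAPK output list, 11 fell and 6 did not pass the threshold, with a median log2 fold change of -0.43; 12 fell when adjusted over the list alone. DUSP6, a phosphatase that dephosphorylates ERK and is itself induced by ERK signalling, fell from 78.4 ± 2.57 to 38.2 ± 1.79 CPM (SD, n = 3 each; log2 fold change -1.04, SE 0.0407, adjusted p = 4.65e-08 by edgeR). ETV5, an ETS transcription factor, fell from 14.5 ± 0.631 to 5.15 ± 0.796 CPM (log2 fold change -1.49, SE 0.104, adjusted p = 4.98e-06). SPRY and SPRED proteins restrain RAS signalling, and SPRY4 (-1.56), SPRY1 (-0.60), SPRED2 (-0.52), SPRED1 (-0.42) and SPRY2 (-0.31) all had lower log2 values. DUSP4 fell by 0.70, FOSL1 by 0.43, CCND1 by 0.33 and MYC by 0.18 on the log2 scale, MYC from 641 ± 14.5 to 565 ± 6.54 CPM (SD, n = 3 each). EGR1 had a log2 fold change of -0.73 and an adjusted p of 0.0514, and passed without SPNS2 library 3 (-0.97, adjusted p = 0.0307). EPHA2, FOS, DUSP5, PHLDA1 and SPRED3 did not pass with all 6 libraries. Without empty vector library 1, 12 members of the list fell, so a gene not called with all 6 libraries was called there. Without empty vector library 2, 9 fell. The list as a whole passed with camera at the preset correlation (adjusted p = 4.50e-07) and not with an estimated correlation (adjusted p = 0.0739 with an estimated correlation). SPRED1 lost its call without empty vector library 2 (adjusted p = 0.0949) and without SPNS2 library 2 (0.0759). CCND1 lost it without empty vector library 2 (0.146) or 3 (0.109) and without SPNS2 library 1 (0.0872) or 3 (0.140).

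Components of the MAPK cascade itself and other early response genes were tested as separate lists. Of 28 cascade genes, 4 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.785). MAP2K6, a kinase of the p38 arm, rose from 1.94 ± 0.177 to 3.53 ± 0.00881 CPM (SD, n = 3 each). MAP2K6 also passed without each single library, but the counts of the cascade did not hold: 2 rose and 1 fell without empty vector library 1, 4 rose without empty vector library 2, 1 rose and 1 fell without empty vector library 3 or SPNS2 library 3, 1 rose and 2 fell without SPNS2 library 1, and 2 rose and 3 fell without SPNS2 library 2. Among 20 immediate early genes, 7 fell and 2 rose, with 9 falling and 2 rising adjusted over the list alone. JUN fell from 41.8 ± 1.68 to 26.0 ± 0.727 CPM, JUND from 147 ± 2.90 to 121 ± 2.39 CPM and KLF6 from 51.6 ± 1.69 to 42.9 ± 1.16 CPM (SD, n = 3 each). ZFP36, which destabilises AU-rich mRNAs, was an exception (0.28), named after its value was seen. It also passed without each single library, and 1 member rose in each of those fits. The immediate early list passed camera (adjusted p = 0.00108) but not with an estimated correlation (adjusted p = 0.0739 with an estimated correlation).

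**Figure D2:**
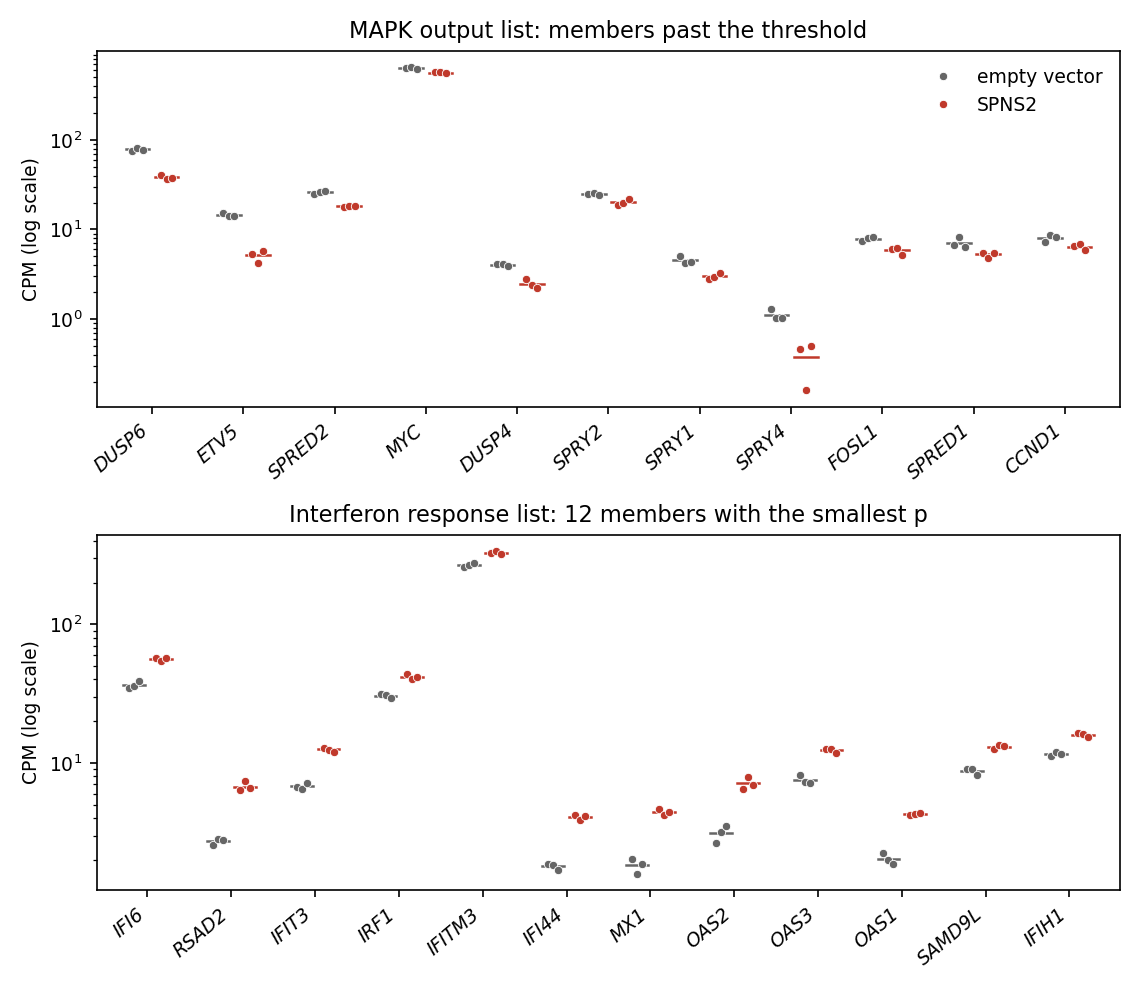
CPM (log axis) of the 11 MAPK output genes that passed the threshold and of the 12 interferon response genes with the smallest p. Points are single libraries and lines are means of 3 libraries per group; DUSP6 fell from 78.4 to 38.2 CPM and IFIT3 rose from 6.83 to 12.5 CPM.

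Genes that make, degrade and move sphingosine phosphate showed single changes without a shift of the list. Of 13 tested genes, 3 rose and 1 fell, also adjusted over the list alone, and camera gave an adjusted p of 0.513. ASAH1, the acid ceramidase that releases sphingosine, rose from 172 ± 8.06 to 224 ± 3.09 CPM (SD, n = 3 each; log2 fold change 0.38, adjusted p = 2.70e-05 by edgeR). SPHK1, which phosphorylates sphingosine, fell by 0.27 on the log2 scale (SE 0.0358, adjusted p = 0.000362 by edgeR). PLPP3, a lipid phosphate phosphatase, rose by 0.38 on the log2 scale. The rise of SPNS3, a paralog of SPNS2, by 0.39 (adjusted p = 0.0356) passed only narrowly: without empty vector library 1 or 2 the adjusted p was 0.0872 or 0.128, and without SPNS2 library 1, 2 or 3 it was 0.129, 0.0616 or 0.0739. SPHK2, SGPL1, SPNS1, MFSD2B, ABCC1, PLPP1, PLPP2, ACER2 and ACER3 did not pass, and SGPP1 was not analysed here.

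Receptors for sphingosine phosphate differed by less than the spread between replicates could resolve. S1PR4 was at 52.4 ± 1.61 CPM with the empty vector and 55.1 ± 1.43 CPM with SPNS2, S1PR3 at 23.4 ± 0.826 and 24.4 ± 0.830 CPM, and S1PR2 at 4.10 ± 0.667 and 4.29 ± 0.182 CPM (SD, n = 3 each). S1PR1 had 0 counts and S1PR5 had 2 counts over the 6 libraries. In the receptor and signalling list of 14 tested genes, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.513). Of these, 2 rose without empty vector library 3 or SPNS2 library 2, and 1 fell without empty vector library 2 or 3 or SPNS2 library 1, 2 or 3. ARRB2, an arrestin, fell by 0.20 and RAC1, a small GTPase, rose by 0.22 on the log2 scale. Ceramide and sphingolipid synthesis genes went both ways, with 6 of 27 up and 5 down, the same adjusted over the list alone (camera adjusted p = 0.785), and 3 up without SPNS2 library 1. SMPD1, acid sphingomyelinase, rose from 8.74 ± 1.09 to 13.1 ± 0.430 CPM, and GALC rose by 0.28 on the log2 scale, while CERS1, a ceramide synthase, fell by 0.27 and DEGS1, which makes ceramide from dihydroceramide, by 0.25.

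Interferon response genes rose together. Of 36 tested genes, 25 rose, 1 fell and 10 did not pass, with a median log2 fold change of 0.48; 28 rose and 1 fell adjusted over the list alone. RSAD2, the antiviral enzyme viperin, rose from 2.74 ± 0.147 to 6.77 ± 0.547 CPM, IFIT3 from 6.83 ± 0.341 to 12.5 ± 0.413 CPM, IFI6 from 36.6 ± 2.34 to 56.1 ± 1.21 CPM and the transcription factor IRF1 from 30.4 ± 1.09 to 41.8 ± 1.68 CPM (SD, n = 3 each). The list passed camera at the preset correlation (adjusted p = 3.28e-14) and with an estimated correlation (adjusted p = 0.0267 with an estimated correlation). The gene that fell was IRF7, named after its value was seen, with 3.94 ± 2.24 CPM in the empty vector libraries and 1.85 ± 0.600 CPM in SPNS2 (SD, n = 3 each; adjusted p = 0.0440 by edgeR). IRF7 did not pass without empty vector library 3 (log2 fold change -0.51, adjusted p = 0.183) or without SPNS2 library 1, 2 or 3 (0.0553, 0.0996 and 0.155).

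Genes of class I antigen presentation rose as well. Of 10 tested, 7 rose and 3 did not pass, also adjusted over the list alone, with a median log2 fold change of 0.24 (camera adjusted p = 0.00120; adjusted p = 0.0739 with an estimated correlation). HLA-B rose from 46.0 ± 0.562 to 68.7 ± 4.42 CPM (SD, n = 3 each), and TAPBP, which loads peptides onto class I molecules, rose by 0.50 on the log2 scale. The peptide-trimming enzymes ERAP2 and ERAP1 rose by 0.26 and 0.22 on the log2 scale. HLA rows are uncertain, since reads of near-identical genes and alleles can be divided among rows: HLA-C had 3 counts over the 6 libraries. TAP2 had 0 counts. NF-kB and inflammatory genes did not pass as a list (19 tested, camera adjusted p = 0.985). In that list 1 gene rose and 1 fell, and both calls were gone adjusted over the list alone and without empty vector library 1 or 3 or SPNS2 library 1, 2 or 3. Without empty vector library 2, 1 fell.

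Most tested proliferation genes were lower with SPNS2. In the DNA replication, G1 and S list, 25 of 30 genes fell (26 adjusted over the list alone), with a median log2 fold change of -0.21. In the G2 and mitosis list, 21 of 30 fell (25 adjusted over the list alone), with a median of -0.20. TYMS, thymidylate synthase, fell from 204 ± 3.14 to 159 ± 2.62 CPM, MCM10 from 70.2 ± 0.622 to 53.6 ± 0.909 CPM, TOP2A from 263 ± 5.66 to 211 ± 3.05 CPM and PLK1, a mitotic kinase, from 88.2 ± 1.80 to 69.7 ± 1.33 CPM (SD, n = 3 each). CDC45 fell by 0.37, UHRF1 by 0.31, CDC20 by 0.28 and MKI67 by 0.25 on the log2 scale. Both lists passed camera at the preset correlation (adjusted p = 7.19e-14 and 2.13e-11) and with an estimated correlation (adjusted p = 0.0272 and 0.0267 with an estimated correlation).

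Genes of growth and of amino acid supply fell too. In the ATF4 and integrated stress response list, 19 of 25 genes fell, with 19 falling and 1 rising adjusted over the list alone, and a median log2 fold change of -0.21 and 1 riser without SPNS2 library 3 (camera adjusted p = 2.63e-09; adjusted p = 0.0272 with an estimated correlation). DDIT4, an mTOR inhibitor, fell from 68.5 ± 0.620 to 48.8 ± 0.862 CPM, and STC2 fell by 0.39, the pseudokinase TRIB3 by 0.35 and the amino acid transporter SLC7A5 by 0.27 on the log2 scale. Of 27 MYC targets in ribosome biogenesis, 19 fell (23 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 2.57e-09; adjusted p = 0.0726 with an estimated correlation). DKC1 and MRTO4 each fell by 0.21, and NOLC1 and NCL each by 0.17. In serine and one-carbon metabolism, 8 of 14 genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000801; adjusted p = 0.0739 with an estimated correlation). SHMT2 fell from 271 ± 4.78 to 211 ± 3.43 CPM and PHGDH, the first enzyme of serine synthesis, from 421 ± 6.77 to 354 ± 6.69 CPM (SD, n = 3 each). Without empty vector library 3, 2 rose.

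Heat shock and energy metabolism genes were tested as separate lists. Of 10 heat shock genes, 9 fell, also adjusted over the list alone, with a median log2 fold change of -0.13 (camera adjusted p = 9.41e-05; adjusted p = 0.113 with an estimated correlation). HSPH1 fell by 0.18 and the chaperonin HSPD1 by 0.13. Of 23 glycolysis genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.000875; adjusted p = 0.125 with an estimated correlation). HK1 fell from 194 ± 6.01 to 160 ± 4.68 CPM and ENO1, an abundant glycolytic enzyme, from 1410 ± 26.8 to 1238 ± 30.8 CPM (SD, n = 3 each). The riser, PFKFB4 (0.16), did not pass without SPNS2 library 3 (adjusted p = 0.0528). Of 33 oxidative phosphorylation genes, 6 fell (4 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0274; adjusted p = 0.334 with an estimated correlation). NDUFB9 fell by 0.20 and SDHB by 0.15 on the log2 scale. This list was not called without empty vector library 3 (adjusted p = 0.155), without SPNS2 library 2 (0.0835) or at a mean CPM of at least 5 (0.0632), and 3 members fell without SPNS2 library 1.

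**Figure D3:**
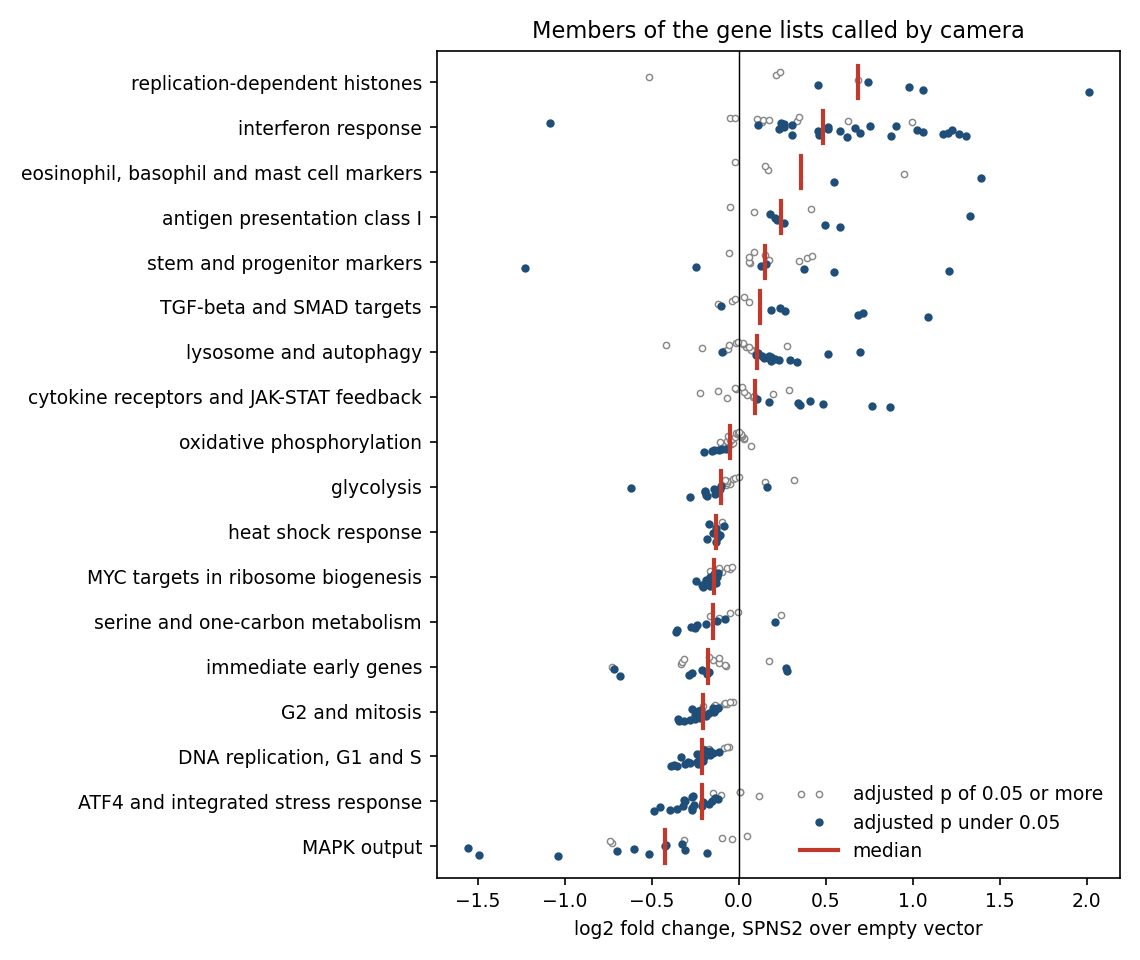
Log2 fold change (SPNS2 over empty vector) of each tested member of the 18 gene lists that passed camera at the preset correlation. Points are genes, filled where the adjusted p was under 0.05, and red lines are list medians, from -0.43 for MAPK output to 0.69 for replication-dependent histones.

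Stem, progenitor and mast cell markers were tested as lists of their own. KIT, the stem cell factor receptor and an abundant transcript of these cells, rose from 1567 ± 21.4 to 2287 ± 38.6 CPM (SD, n = 3 each; log2 fold change 0.55, SE 0.0207, adjusted p = 3.68e-08 by edgeR). FLT3, another receptor tyrosine kinase of progenitors, rose by 1.21 on the log2 scale and BAALC from 57.1 ± 1.95 to 74.1 ± 2.34 CPM, while TAL1 fell from 4.67 ± 0.647 to 1.99 ± 0.0826 CPM (SD, n = 3 each). CD34, named after its value was seen, fell by 0.25 on the log2 scale. In the stem and progenitor list 5 of 17 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.125 with an estimated correlation, and 0.0530 without empty vector library 1). In the eosinophil, basophil and mast cell list 2 of 6 rose, KIT and TPSB2, also adjusted over the list alone (camera adjusted p = 0.00977, and 0.190 with an estimated correlation). Only these 6 of the 19 listed genes could be tested. Among the rest, FCER1A, CPA3 and HDC, chosen after their values were seen, had 0, 3 and 3 counts over the 6 libraries. The list result therefore does not show a rise of mast cell markers as a whole. TPSAB1, with a log2 fold change of 0.95, did not pass (adjusted p = 0.104); without empty vector library 2 it was 1.57 with an adjusted p of 0.0141, and 3 members then rose.

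Monocyte, granulocyte and other lineage lists did not pass camera in the main fit with all 6 libraries, but fry called 3 of them. Of 14 monocyte and macrophage markers, 4 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.513; fry adjusted p = 0.0299, down). CD68 rose from 54.9 ± 1.94 to 76.9 ± 2.82 CPM and CSF1R, the receptor of macrophage colony-stimulating factor, from 3.83 ± 0.296 to 7.04 ± 0.250 CPM, while the transcription factor IRF8 fell from 14.6 ± 1.05 to 9.73 ± 0.209 CPM (SD, n = 3 each). Of 12 granulocyte markers, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.834). The riser, CSF3R, rose by 0.26 on the log2 scale (adjusted p = 1.61e-05), and 2 fell without empty vector library 1. The fall of PRTN3 (-0.17, adjusted p = 0.0289) was not called without empty vector library 2 (0.101) or 3 (0.113) or without SPNS2 library 1 (0.0709), 2 (0.107) or 3 (0.0574). Of 5 erythroid genes, 2 rose, also adjusted over the list alone (camera adjusted p = 0.104, and 0.0476 without empty vector library 3; fry adjusted p = 0.000390, up), among them TFRC, the transferrin receptor, from 132 ± 2.74 to 208 ± 2.30 CPM (SD, n = 3 each). Of 5 megakaryocyte and platelet genes, 2 rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.454), and only NFE2 also rose without empty vector library 1, 2 or 3 and without SPNS2 library 1, 2 or 3, in each of which 1 rose. Of 13 genes related to the core binding factor, 4 rose and 1 fell, also adjusted over the list alone. For this list camera gave an adjusted p of 0.0560, and 0.0389 without SPNS2 library 3. With all 6 libraries corrected for GC content and transcript length, camera gave 0.0388, up. Fry gave an adjusted p of 0.000925, up. PTPRM fell by 0.64 and NT5E rose by 1.01 on the log2 scale. MYH11, the listed partner gene of the fusion, had 39 counts over the 6 libraries and was not tested. It was named after its value was seen. The gene counts therefore do not show the fusion transcript of these cells.

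Lists of T and NK cell, B cell and packaging cell markers did not pass camera. Of 5 T and NK cell genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.985), and without empty vector library 1 or 3 or SPNS2 library 1, 2 or 3 only the fall was called, with CD8A falling from 3.66 ± 0.485 to 2.27 ± 0.339 CPM (SD, n = 3 each). Of 6 B cell genes, 1 rose (2 adjusted over the list alone; camera adjusted p = 0.576): CD79B went from 4.08 ± 0.230 to 5.92 ± 0.598 CPM (SD, n = 3 each). Of 5 kidney and epithelial packaging cell genes, 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.427; called down by fry, adjusted p = 0.0319), with CDH2 down by 0.47 and EPCAM up by 0.19 on the log2 scale.

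Lysosome, cytokine receptor and TGF-beta lists rose. Of 30 lysosome and autophagy genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median log2 fold change of 0.11 (camera adjusted p = 0.00121; adjusted p = 0.0739 with an estimated correlation), and 9 rose without SPNS2 library 2. The fall was not called without empty vector library 2 or 3 or SPNS2 library 1 or 2. The protease CTSD rose from 518 ± 4.37 to 654 ± 15.2 CPM (SD, n = 3 each), NPC2 by 0.30 and the sphingolipid activator precursor PSAP by 0.18 on the log2 scale. Of 20 cytokine receptor and JAK-STAT feedback genes, 8 rose, also adjusted over the list alone (camera adjusted p = 0.00166; adjusted p = 0.0739 with an estimated correlation), and 5 rose without SPNS2 library 3. The kinase PIM1 rose by 0.87 on the log2 scale and IL6R from 18.9 ± 0.514 to 32.1 ± 0.642 CPM (SD, n = 3 each). Of 12 TGF-beta and SMAD targets, 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0168; adjusted p = 0.125 with an estimated correlation, and 0.0530 without empty vector library 1). The fall was not called without empty vector library 1 or 3 or SPNS2 library 1 or 3. ID2 rose by 1.09, PMEPA1 by 0.72 and SKIL by 0.68 on the log2 scale.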

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

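All alternatives here were planned before the data were examined. No called gene among the 278 tracked, no called list and no vector value changed direction under any alternative run. The number of genes changed between SPNS2 and empty vector was 1723 at an adjusted p under 0.01, 125 with an absolute log2 fold change above 1, and 87 with glmTreat against a log2 fold change of 0.5. These thresholds are stricter by construction. The number of lists was 4 with camera at an estimated correlation and 28 with fry. Scaling by DESeq2 size factors gave 3260 genes, total counts alone 3217 (1725 higher and 1492 lower), library sizes without the vector row 3260, limma voom 3238, no low-count filter 3205 and a mean CPM of at least 5 gave 3061. The DESeq2 Wald test gave 2350 genes, of which 2320 were also called by edgeR, and 28 of the 232 called genes among those tracked missed its threshold. Leaving out each library in turn gave 2246 to 2738 genes, 16 to 19 lists and a vector SPNS2 log2 fold change of 12.05 to 13.83. A fit with the replicate number as a block gave 2723 genes, 18 lists and a vector log2 fold change of 12.61. Libraries with the same number showed no clear shared deviation: the correlations of deviations were 0.0606, -0.0911 and -0.235. With 3 libraries per group, these values cannot exclude that the numbers pair the samples. Only library 1 correlated best with its own number. Depth limits genes near the filter most, where a few counts per library set the value, as for the vector sequence in the empty vector libraries.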

Other observations

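The tests of NF-kB genes and of features trading reads with CDK7 were chosen after the result was seen, and CDK7 itself was singled out after its values were seen. Gene lists for cell death and stress, not described so far, did not pass camera, while fry called 3 of these 4 lists up. Of 23 apoptosis regulators, 8 rose (9 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.192; fry adjusted p = 0.00450). The survival factor BCL2 rose from 72.7 ± 2.57 to 97.5 ± 1.32 CPM, and the BH3-only genes BMF, BIK and BCL2L11, which promote cell death, rose by 0.63, 0.47 and 0.25 on the log2 scale (SD, n = 3 each). Of 21 p53 targets, 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.513; fry adjusted p = 0.00286). TP53INP1 rose from 4.08 ± 0.178 to 7.29 ± 0.0341 CPM and CCNG1 from 168 ± 4.86 to 196 ± 4.27 CPM (SD, n = 3 each). Of 15 hypoxia genes, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.513; fry adjusted p = 0.0103), with NDRG1 up by 0.37. Of 20 unfolded protein response genes, 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.704), with HERPUD1 down by 0.26. Without any 1 of the empty vector libraries 1, 2 and 3 and SPNS2 libraries 1, 2 and 3, 2 p53 targets rose, and 1 fell without empty vector library 1 or 3 or SPNS2 library 2 or 3. Of the apoptosis genes, 1 fell without empty vector library 2 or SPNS2 library 1. Of the hypoxia genes, 1 fell without empty vector library 2 or 3 or SPNS2 library 2 or 3, and of the unfolded protein response genes 1 rose without empty vector library 3 or SPNS2 library 1 or 2.

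Replication-dependent histone rows rose while the proliferation lists fell. Of 9 tested histone genes, 5 rose, also adjusted over the list alone, with a median log2 fold change of 0.69 (camera adjusted p = 0.00830; adjusted p = 0.129 with an estimated correlation), and 3 rose without empty vector library 2 or 3 or SPNS2 library 1. H2BC5 rose from 0.259 ± 0.0652 to 1.06 ± 0.153 CPM and H2BC21 from 1.33 ± 0.299 to 2.79 ± 0.286 CPM (SD, n = 3 each). These rows are uncertain, since histone genes are near-identical and most of their transcripts lack the poly(A) tail that the library kit selects. The 2 lipid synthesis lists did not pass camera, while fry called both down. Of 24 cholesterol synthesis genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0760; fry adjusted p = 0.00379), with FDPS down by 0.19. Of these, 2 rose without empty vector library 1 or SPNS2 library 1 or 3, and 4 fell without empty vector library 2 or SPNS2 library 1 or 3. Of 20 genes of fatty acid and lipid synthesis, 7 fell, also adjusted over the list alone (camera adjusted p = 0.237; fry adjusted p = 0.0299), and 1 rose without SPNS2 library 1. FASN, fatty acid synthase, fell from 697 ± 23.5 to 589 ± 19.9 CPM and the elongase ELOVL6 from 30.1 ± 1.22 to 22.9 ± 1.04 CPM (SD, n = 3 each). Among migration genes, 4 of 15 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.736), with the integrin ITGB2 down by 0.28 and 2 risen members without empty vector library 2 or 3 or SPNS2 library 1 or 2. Of 36 ribosomal protein genes, 3 fell (2 adjusted over the list alone; camera adjusted p = 0.513), with RPL8 down by 0.12. Of 13 mitochondrially encoded genes, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.985): MT-CO1 up by 0.11 and MT-ND6 down by 0.30, with 4 falling without empty vector library 1 and 2 without SPNS2 library 2. For the lists MAPK cascade, sphingosine phosphate metabolism, ceramide synthesis, mitochondrially encoded genes, NF-kB, granulocyte, T and NK cell and B cell markers, the median, the mean and camera's direction were not all of the same sign.

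The fall of the MAPK output, proliferation, MYC and ATF4 lists was weighed against technical explanations. Each library was corrected for GC content and transcript length. The largest camera adjusted p of these 5 lists at the preset correlation was then 3.57e-06, with all 5 still downward. This argues against GC and length trends as the whole cause. With an estimated correlation, MAPK output (camera adjusted p = 0.0739) and MYC targets (0.0726) did not pass before the correction, and that setting was not run after it. The correction moved other genes, with 3549 called after it, of which 3014 were called before. A broad DNA copy number loss that lowered these genes directly would place them in regions that are lower as a whole. Of 95 fallen members, 0% lay in a window of 51 neighbouring genes with a median log2 fold change under -0.1, and the lowest window median was -0.0866. No window went under -0.1, so 0% was fixed for any set of genes. The values show no broad region lower by that much. Smaller copy number differences, and indirect effects of any such difference, were not tested. An effect of SPNS2 on ERK signalling and growth stays a hypothesis, as does any difference in growth or handling between the populations, which the design does not separate from the vector.

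The rise of the interferon and class I lists was weighed in the same way. After the GC and length correction, the larger camera adjusted p of both lists at the preset correlation was 0.000865, both upward. Before that correction, the class I list did not pass camera with an estimated correlation (adjusted p = 0.0739). An inflammatory response of the kind that raises NF-kB genes would have raised that list, but 1 of 19 tested NF-kB genes rose. That rise was not called adjusted over the list alone. Only 19 of the 28 listed genes could be tested, and inflammatory responses of other kinds were not tested. Transcription of interferon genes in these cells could account for the rise of both lists. The 3 counts of such genes over the SPNS2 libraries, against 0 with the empty vector, are too few to tell. A response to the vector RNA or its product may also be present and was not tested.

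The CDK7 estimate stood at 0.311, 0.386 and 0.559 CPM in the empty vector libraries and at 15.6, 0.159 and 24.8 CPM in SPNS2. Its call (log2 fold change 5.02, adjusted p = 0.00740) comes with overlapping groups. Over the alternatives its adjusted p ran from 1.12e-06 without SPNS2 library 2 to 0.440 with limma voom, the only one that did not call it. In 53 features with a group mean of at least 1 CPM, the highest library of a group was over 5 times the sum of the lowest and 0.1 CPM. Of these 53, CDK7 was the one that was called. Below that mean, called genes can also vary widely, though CDKN1C falls short of this rule: it was at 1.22, 0.211 and 1.24 CPM in the empty vector libraries. PPP1R10, TRIM27 and LY6E, chosen after their values were seen, also jumped, up to 113, 84.0 and 40.4 CPM. The test first written looked for another feature whose sum with CDK7 varies little, and PTPRF gave a coefficient of variation of 6.32%, under the bound of 10%. That test decides nothing, because PTPRF is so abundant (197 CPM) that it dilutes CDK7, a rule set after the value was seen. A second test asked which feature cancels the deviations of CDK7, and HCFC1, the best of 11847, left 0.0993 of the squared deviation, under a first bound of 0.1 that was replaced by 0.02 after this value was seen, because the best of so many can come close by chance. Reads traded with another feature cannot be told apart from other causes of the jump.

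Of the 10 ways to split the 6 libraries 3 against 3, only the real split, 1 of 10, called 3263 genes, and the highest of the others called 1. For lists the real split called 18 and the others 3 to 10. Every other split puts libraries of both groups on each side, so the group difference widens the spread within its sides. Few gene calls were therefore likely there in advance. Part of the group difference can also remain between the sides, so these splits do not show how many calls arise without one. With 10 splits the share cannot go under 0.1. The mean vector SPNS2 level over the 3 empty vector libraries, of which 2 held counts, was 0.0145% of the mean level in SPNS2 libraries.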
